A study of Mus musculus with 12 samples.

How the data were processed

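The samples were whole ears of wild-type and Krt17-null mice, 3 libraries in each of 4 groups, prepared per the labels from 484 ng of RNA with rRNA depletion and a random-primed kit. The values analysed were the integer counts per gene that the authors deposited, the unit being the read count. The submitters' processing notes name STAR 2.7.10a, edgeR 3.36, limma 3.50.3, R 4.1.2 and the genome build GRCm39. The counting program, the strand setting, the handling of multiply mapped reads and the annotation release are not given in the sources used here. Gene names, chromosome membership and transcript similarity were taken from GENCODE M21, an annotation of the earlier build GRCm38. Of 56691 gene identifiers 52073 matched a name and 4618 did not, and the latter held 0.915% to 1.85% of counts per library. In all, 19714 genes had no count in any library.

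Counts were normalised by TMM factors and filtered with filterByExpr in edgeR 4.0.16 (minimum count 10), which left 21775 genes. A quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 12 libraries in R 4.3.3, and 5 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. The contrasts were TPA against acetone in each genotype, Krt17 null against wild type under each treatment, and their interaction. A set of 35 gene lists with 477 genes, 474 of them in the table, was tested with camera (preset correlation 0.01, and an estimated correlation) and fry in limma 3.58.1, with adjustment over the lists. The grouping, contrasts, lists, threshold and alternatives were fixed before the data were examined. The list score was the mean log2 CPM with a prior count of 2, compared between 3 and 3 libraries by exact permutation, for which the smallest possible p is 0.1. The size of the TPA response was the slope through the origin of the null on the wild-type log2 fold changes, among genes called for TPA averaged over both genotypes. The slope of wild type on null, and the slope that the standard errors alone would give with equal responses, were added after the result was seen.

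Genes were named by rule: Krt17; the 10 largest changes in each direction among genes with an adjusted p under 0.05, a mean of at least 5 CPM over all libraries compared, complete separation of the groups and no clone or predicted-gene name; up to 4 members of each list by p; and 13 genes fixed beforehand. The fixed genes were Prkca, S100a8, S100a9, Cxcl1, Cxcl2, Cxcl3, Cxcl5, Csf3, Il1b, Krt6a, Krt16, Cxcr2 and Csf3r. Where a comparison had few calls all were named, a choice made after the values were seen. A gene with no count in 1 group is given as at least the fold over a floor of 3 counts in that group, and a gene with 1 to 3 counts as a ratio with a counting interval. Reads were amplified without molecular barcodes and are not independent molecules, so these floors and intervals cover counting error only. Of 530 named and listed genes, 49 have a transcript of another gene at least 95% identical over at least 50% of their longest transcript, a search added after the results were seen. Those of them named in the text are called uncertain where their change is first given.

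The alternatives were leaving out each library in turn, RLE size factors, limma voom, DESeq2 1.42.0, a stricter filter (1 CPM in 6 libraries), no filter, a 2-fold minimum, fits of 2 groups only, replicate number as a block, the skeletal muscle score as a covariate and 1 surrogate variable from sva 3.50.0. In counts simulated from the fitted dispersions with 100 genes changed at each size, the null against wild-type test under TPA recovered 59% of 2-fold and 90% of 4-fold changes, with 6 false among 164 calls. In that simulation the endothelial markers were lowered 2-fold as well, and their calls are part of the 164. Under acetone it recovered 65% and 98%, with 8 false among 171. In both simulations these changed genes had a mean of at least 1 CPM and lay outside the gene lists. Genes were drawn independently, without shifts shared within a library, so the rates need not hold for the listed genes. Transcripts were compared with blastn 2.17.0, and figures were drawn with matplotlib 3.10.9. A few single-gene results are not reported here.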

Results

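Gene expression was measured by rRNA-depleted RNA sequencing of whole mouse ear after repeated application of TPA, a phorbol ester that activates protein kinase C and inflames skin. Wild-type mice and mice lacking Krt17, the gene of the stress-induced keratin 17, received 2 applications of 20 µl of TPA at 0.2 mg/ml, 24 h apart. The opposite ears received acetone, the vehicle, and tissue was collected 6 h after the last application. The 4 groups (wild-type acetone, wild-type TPA, Krt17-null acetone and Krt17-null TPA) held 3 libraries each, 12 in all. Total counts per library ran from about 29498200 to 38682500. The labels do not say which libraries came from the same animal, so p-values measure the spread between these libraries, part of which can be technical. All pairs of libraries within a group differed by more than counting noise, with chi-square per degree of freedom from 9.61 to 94.1. Treatment separated the libraries along the first principal component, which held 63.9% of the variance. On it the wild-type TPA libraries lay at -93.3, -105 and -87.4, and the Krt17-null TPA libraries at -39.9, -46.3 and -89.2, so Krt17-null TPA replicate 3 lay among the wild-type TPA libraries. Mean Ddx3y, a Y-linked gene, ran from 58.2 to 74.5 CPM (counts scaled to library size) in the 4 groups and mean Xist from 0.0615 to 0.0862 CPM.

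Krt17 itself followed the genotype labels in every library. It averaged 390 ± 46.5 CPM (SD, n = 3) in wild-type acetone ears and 2517 ± 362 CPM (n = 3) in wild-type TPA ears. In Krt17-null ears it averaged 10.7 ± 2.97 CPM (n = 3) with acetone and 36.5 ± 3.43 CPM (n = 3) with TPA, which is 2.74% and 1.45% of the wild-type means. The Krt14 transcript is 89.1% identical to that of Krt17 over 957 aligned bases and the Krt16 transcript 81.2% over 959, so the small counts left in null libraries are uncertain where reads can be shared between keratin genes.

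**Figure D1:**
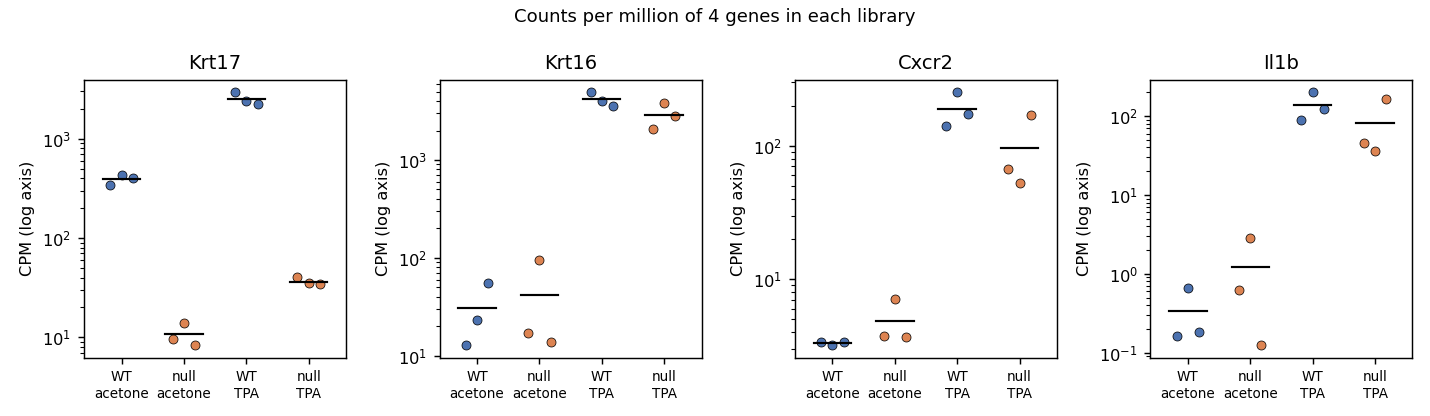
CPM (log axis) of Krt17, Krt16, Cxcr2 and Il1b in each of the 12 libraries, by group, with points for libraries and lines for group means. Krt17 averaged 390 CPM in wild-type acetone and 36.5 CPM in Krt17-null TPA ears, while Krt16 averaged 2897 CPM in Krt17-null TPA and 4149 CPM in wild-type TPA ears.

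The first comparison asks how wild-type ear responds to repeated TPA. Genes of neutrophils, of the factors that attract them, of wound-activated keratinocytes and of the cell cycle rose, and genes of fat, muscle and cartilage fell. Krt6a and Krt16, keratins of stressed epidermis with near-identical copies that make their counts uncertain, rose 58.4-fold (log2 fold change 5.87, SE 0.47) and 136-fold (7.09, SE 0.99), and Krt17 rose 6.45-fold. Il1b, the gene of interleukin-1 beta, rose 398-fold (log2 8.64, edgeR adjusted p = 0.000499), and S100a8 and S100a9, alarmins abundant in neutrophils and stressed keratinocytes, rose 335-fold and 175-fold. In the edgeR quasi-likelihood test, 5187 genes were higher and 4370 lower among 21775 tested at an adjusted p under 0.05. With a change of at least 2-fold required as well, the counts were 2477 and 2359. With the skeletal muscle score as a covariate they were 1795 and 1331. That score itself fell with TPA, from 8.42 to 6.27 in wild-type and from 8.41 to 6.64 in Krt17-null ears. Adjusting for it can therefore take away part of the treatment effect.

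Among 20 neutrophil markers, 18 rose and none fell, with a median log2 fold change of 7.93, or 7.37 with genes absent from acetone ears set to the floor of 3 counts over the group. Cxcr2, a neutrophil chemokine receptor, went from 3.33 to 188 CPM (edgeR adjusted p = 3.88e-05) and Csf3r, the receptor of granulocyte colony-stimulating factor, from 2.10 to 451 CPM (edgeR adjusted p = 0.00021). Cxcr1 was at least 65.7-fold higher, and Clec4e, a pattern recognition receptor gene, went from 0.0437 to 26.3 CPM. Stfa2l1, a stefin-like gene with a near-identical copy and so uncertain, was at least 512-fold higher, and Trem1, an amplifier of myeloid activation, went from 0.0933 to 79.2 CPM. The list stood above other genes by camera with a preset correlation (adjusted p = 2.62e-11) and not with an estimated one (adjusted p = 0.198). Of 8 measured granule precursor genes, 4 rose and 1 fell. Lcn2, encoding lipocalin-2, reached 151 CPM, Chil3 36.9 CPM and Ngp at least 59.1-fold its acetone level, whereas Mpo, the myeloperoxidase gene, fell from 23.9 to 4.82 CPM, and the list did not pass (camera adjusted p = 0.115).

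Of 9 neutrophil chemoattractants and growth factors, 8 rose (camera adjusted p = 0.000291; adjusted p = 0.26 with an estimated correlation). Cxcl1 rose 90.8-fold (edgeR adjusted p = 6.78e-05). Cxcl5 went from 0.0409 to 91.7 CPM and Cxcl2 from 0.0547 to 71.1 CPM, while Cxcl3 was at least 834-fold higher. Csf3, the growth factor of neutrophils, went from 0.08 to 5.24 CPM. Of 18 measured inflammatory cytokines, 16 rose (camera adjusted p = 8.66e-13), and this list held with an estimated correlation (adjusted p = 0.00914). Tslp, an epithelial alarm cytokine, went from 1.17 to 21.1 CPM, Il1f9, also called Il36g, from 27.2 to 120 CPM, and Tnf from 2.42 to 18.2 CPM, while Il19 rose 400-fold (95% counting interval 137 to 1943). Of 23 other chemokines, 15 rose and 3 fell (camera adjusted p = 1.63e-06; adjusted p = 0.168 with an estimated correlation). Ccl2, which draws monocytes, went from 0.301 to 79.6 CPM, Ccl12 from 0.477 to 13.5 CPM and Cxcl16 from 25.3 to 53.9 CPM. Ccl4 was at least 1204-fold higher, and Ccl21a, a chemokine of lymphatic vessels whose counts are uncertain because of near-identical copies, fell from 77 to 12.3 CPM.

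Of 15 monocyte and macrophage markers, 11 rose and 2 fell (camera adjusted p = 1.91e-05; adjusted p = 0.26 with an estimated correlation). Cd68 rose from 20 to 150 CPM, Ccr2 from 6.39 to 89.7 CPM and Mrc1, the mannose receptor gene, from 68.1 to 835 CPM, and Mertk, a receptor for dying cells, fell from 28 to 12.6 CPM. Dendritic and Langerhans cell markers were mixed, with 5 of 13 higher and 1 lower, Ccr7 going from 0.59 to 10.7 CPM and Itgax from 6.7 to 74.2 CPM. T cell markers were 4 higher and 2 lower of 14, and mast cell markers 3 higher and 4 lower of 9, with Tpsb2, a mast cell tryptase, down from 23.1 to 9.16 CPM. Neither these lists nor the dendritic list passed camera (adjusted p = 0.248, 0.984 and 0.676 for dendritic, T and mast cells). All of 12 NF-kB feedback and target genes rose (camera adjusted p = 2.5e-14; adjusted p = 0.098 with an estimated correlation), among them Tnfaip3, a brake on NF-kB, from 23.4 to 103 CPM, Nfkb2 from 45.8 to 133 CPM and Bcl3 from 8.97 to 138 CPM.

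Of 19 genes of wound-activated keratinocytes, 18 rose (camera adjusted p = 7.1e-09; adjusted p = 0.198 with an estimated correlation). Has3, a hyaluronan synthase, went from 1.46 to 66.1 CPM and Tgm1, the transglutaminase of the cornified envelope, from 142 to 332 CPM. Of 14 matrix proteases and inhibitors, 13 rose (camera adjusted p = 2.28e-08; adjusted p = 0.157 with an estimated correlation), including Adamts4 from 0.826 to 77.5 CPM, Timp1 from 3.05 to 183 CPM, Mmp12 from 0.625 to 92.6 CPM and the collagenase gene Mmp13 from 0.0837 to 90.1 CPM. Of 10 measured antimicrobial peptides and alarmins, 9 rose (camera adjusted p = 0.000192; adjusted p = 0.198 with an estimated correlation). Slpi, a leukocyte protease inhibitor, went from 2.84 to 327 CPM and Defb3, a beta-defensin, was at least 638-fold higher. All of 20 proliferation genes rose (camera adjusted p = 1.24e-13; adjusted p = 0.198 with an estimated correlation), with Birc5 from 6.77 to 23.6 CPM and Top2a from 40.3 to 162 CPM. Basal keratinocyte markers went both ways, 3 higher and 4 lower of 11, with Krt15, a keratin of quiescent basal and follicle cells, down from 1424 to 211 CPM. Terminal differentiation genes were 5 higher and 9 lower of 25, with Tgm3 up from 61.2 to 186 CPM, and Krt10 down from 11437 to 3638 CPM and Flg2 from 2031 to 527 CPM. Neither of these lists passed camera (adjusted p = 0.118 and 0.186).

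Genes of deeper ear tissue fell in the same libraries. All of 11 adipocyte markers fell (camera adjusted p = 2.62e-11; adjusted p = 0.17 with an estimated correlation), with Plin1, which coats lipid droplets, down from 96.7 to 16.3 CPM and Retn, the resistin gene, from 14.1 to 1.26 CPM. Of 13 skeletal muscle markers, 12 fell (camera adjusted p = 5.41e-05; adjusted p = 0.402 with an estimated correlation), and all of 12 cartilage markers fell (camera adjusted p = 4.21e-07; adjusted p = 0.198 with an estimated correlation). Atp2a1, the calcium pump of fast muscle, fell from 1822 to 339 CPM, and Col9a1, a cartilage collagen gene, from 19.8 to 3.26 CPM. Of 10 fibroblast markers, 7 fell and 1 rose, with Col1a1 down from 7323 to 1039 CPM, and of 11 sebaceous gland genes 8 fell, with Scd3, a lipid desaturase gene, down from 110 to 8.55 CPM. Both lists passed camera (adjusted p = 0.00029 and 1.05e-05) and neither did with an estimated correlation (adjusted p = 0.198 for each). Schwann cell, melanocyte and cholesterol synthesis lists also had lower medians (-1.01, -0.95 and -0.57; camera adjusted p = 5.06e-05, 0.0436 and 0.00179; adjusted p = 0.198, 0.432 and 0.432 with an estimated correlation). Among single genes, the largest falls were of Inmt, a methyltransferase gene (290-fold), Thrsp, a regulator of lipogenesis (76.7-fold), Cyp2e1 (68.7-fold), the hair keratin-associated gene Krtap3-2 (47.6-fold) and Pck1, which encodes phosphoenolpyruvate carboxykinase (32-fold).

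Endothelial adhesion molecules, NRF2 targets, immediate early genes and interferon-stimulated genes had higher medians (2.15, 0.88, 0.78 and 1.24; camera adjusted p = 0.000178, 0.00248, 4.89e-05 and 0.000944). With an estimated correlation none of these passed (adjusted p = 0.141, 0.198, 0.215 and 0.432). Icam1 rose from 20.5 to 101 CPM and Selp, encoding P-selectin, from 4.21 to 37 CPM. Slc7a11, the cystine transporter gene, rose from 4.81 to 172 CPM and Junb from 215 to 674 CPM. Prkca, which encodes protein kinase C alpha, had 44.1 CPM with acetone and 36.9 CPM with TPA (edgeR adjusted p = 0.0617). Prkcd rose from 103 to 163 CPM (edgeR adjusted p = 0.00103), and the list of 9 protein kinase C genes did not pass (camera adjusted p = 0.804). Endothelial, hair follicle, erythrocyte, mitochondrially encoded, sex-linked and Krt17-neighbour lists did not pass (camera adjusted p = 0.33, 0.469, 0.463, 0.533, 0.984 and 0.508).

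**Figure D2:**
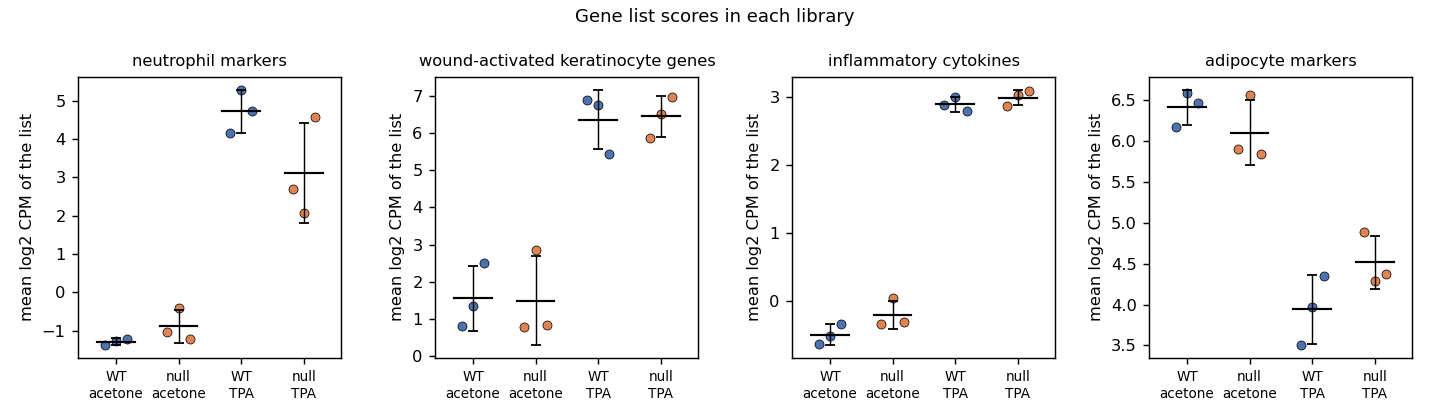
Mean log2 CPM of 4 gene lists in each library, by group, with points for libraries, lines for group means and bars for SD (n = 3). For the neutrophil markers the 3 Krt17-null TPA libraries lay at 2.69, 2.07 and 4.58 and the wild-type TPA libraries at 4.15, 5.27 and 4.74.

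The second comparison asks how Krt17-null ear responds to the same treatment. It showed the same broad program: neutrophil genes, chemoattractants, wound keratins and cell cycle genes rose, and adipocyte, muscle and cartilage genes fell. Krt6a rose 34.1-fold (log2 5.09, SE 0.45), Krt16 68.6-fold (6.10, SE 0.95) and Il1b 66.8-fold (6.06, SE 1.02). S100a8 rose 102-fold and S100a9 70.6-fold. In the edgeR test 4307 genes were higher and 3419 lower. With at least 2-fold required the counts were 1830 and 1438, and with the muscle score as a covariate 1304 and 972.

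Of 20 neutrophil markers 17 rose, with a median of 5.65, or 5.14 with genes absent from acetone ears at the floor (camera adjusted p = 3.18e-09; adjusted p = 0.259 with an estimated correlation). Cxcr2 went from 4.86 to 96.3 CPM (edgeR adjusted p = 0.000279), Csf3r from 3.27 to 203 CPM and Clec4e from 0.225 to 13.4 CPM, and Cxcr1 was at least 47.9-fold higher. All of 9 chemoattractants and growth factors rose (camera adjusted p = 0.000144; adjusted p = 0.183 with an estimated correlation). Cxcl1 rose 59.2-fold, Cxcl2 60.6-fold and Cxcl5 610-fold, and Csf3 rose 102-fold (95% counting interval 34.6 to 498). Of 18 inflammatory cytokines 16 rose (camera adjusted p = 1.54e-17; adjusted p = 0.00151 with an estimated correlation). Tslp went from 1.24 to 25.2 CPM, Il19 from 0.0769 to 19.3 CPM and Il1f9 from 31.7 to 114 CPM. All of 12 NF-kB genes rose (camera adjusted p = 2.06e-16; adjusted p = 0.0447 with an estimated correlation), with Tnfaip3 from 27.6 to 112 CPM and Bcl3 from 11.2 to 134 CPM.

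Monocyte and macrophage markers were 10 higher and 1 lower of 15 (camera adjusted p = 0.000225; adjusted p = 0.352 with an estimated correlation), with Cd68 from 19.3 to 71.6 CPM and Mrc1 from 70.9 to 448 CPM. Of 19 genes of wound-activated keratinocytes 18 rose (camera adjusted p = 3.63e-14; adjusted p = 0.164 with an estimated correlation), with Has3 from 1.85 to 77.3 CPM and Hbegf, an EGF receptor ligand, from 8.41 to 117 CPM. All of 20 proliferation genes rose (camera adjusted p = 9.64e-16; adjusted p = 0.173 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, from 19.1 to 72.2 CPM. Saa3, an acute phase gene, rose 153-fold, and Defb3 and Uox, the urate oxidase gene, rose 133-fold and 108-fold. All of 11 adipocyte markers fell (camera adjusted p = 1.85e-08; adjusted p = 0.183 with an estimated correlation), with Plin1 from 88 to 24.2 CPM. Of 13 muscle markers 10 fell and of 12 cartilage markers 8 fell (camera adjusted p = 5.25e-05 and 0.000363; adjusted p = 0.366 and 0.348 with an estimated correlation). Atp2a1 went from 1822 to 460 CPM, and Casq1 and Tcap, genes of the muscle contraction apparatus, fell 6.37-fold and 7.17-fold. Prkca had 42.1 CPM with acetone and 41 CPM with TPA (edgeR adjusted p = 0.805).

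Most of the response was common to both genotypes. Of the genes called, 6628 moved the same way in both genotypes, 3736 up and 2892 down, where independent lists of these sizes would share 1026 and 686. Another 2927 were called in wild type only, 1096 in Krt17-null only and 2 in opposite directions. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.868. A call in one genotype only is no test of a difference, which the interaction below gives.

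**Figure D3:**
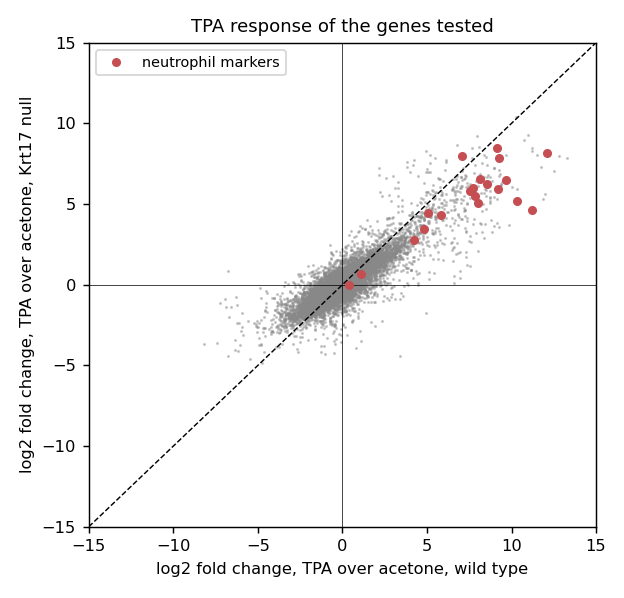
Log2 fold change with TPA in wild type (x axis) and in Krt17 null (y axis) for each of 21775 genes tested, with the line of equal change dashed and the 20 neutrophil markers in red. Across genes r was 0.868. The neutrophil markers had a median of 7.93 in wild type and 5.65 in Krt17 null.

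The third comparison sets Krt17-null against wild-type ears given acetone alone. Few genes passed: edgeR called 3 higher and 2 lower in the null ears. Krt17 was 36.4-fold lower (log2 -5.19, SE 0.21, edgeR adjusted p = 4.99e-09). The other 4 fell outside the rule for named genes and are given because the count is small. Gm4875, a pseudogene, had 1 count in null acetone libraries against 197 in wild type, a ratio of 218 (95% counting interval 38.7 to 8650, edgeR adjusted p = 7.7e-06). Its transcript is 95.7% identical to that of Lasp1, a gene of an actin-binding protein, over 792 aligned bases, so its counts are uncertain. Glns-ps1, a pseudogene 96.8% identical to the glutamine synthetase gene Glul over 1126 aligned bases, was 11.2-fold higher in null ears (edgeR adjusted p = 2.69e-05). The counts of Glns-ps1 are uncertain as well. Pyy, which encodes peptide YY, had 4.53 ± 2.61 against 0.382 ± 0.062 CPM (edgeR adjusted p = 0.0302), and Gbp5, an interferon-inducible GTPase gene, 6.87 ± 2.38 against 1.48 ± 0.483 CPM (edgeR adjusted p = 0.0337). Pyy and Gbp5 each lost the call without 1 library in 7 of 12 cases. At an unadjusted p under 0.05 there were 875 genes, where chance gives 1089, and DESeq2 called 15 higher and 10 lower, including the same 5. Leaving out Krt17-null TPA replicate 1, Krt17-null acetone replicate 1 or 3, or any wild-type acetone library left 1 gene higher, and leaving out wild-type acetone replicate 1 gave 9 lower.

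Several lists shifted as groups under acetone with the preset correlation of camera and none did with an estimated one. Gbp5 was the only gene of the lists below that edgeR called, while DESeq2 called 1 interferon-stimulated gene higher and 2 fibroblast markers lower. Of 25 interferon-stimulated genes 22 had higher values in null ears, with a median of 0.31 (camera adjusted p = 1.41e-08; adjusted p = 0.391 with an estimated correlation), and adjusted over the list alone 3 were higher. Of 23 other chemokines 18 had higher values (median 0.59, camera adjusted p = 3.72e-06; adjusted p = 0.391 with an estimated correlation), those with the smallest p being Ccl27a, the chemokine of keratinocytes for skin-homing T cells, uncertain because of a near-identical copy (24.6 against 15.6 CPM, edgeR adjusted p = 0.933), and Cxcl9 (2.25 against 1.06 CPM). Of 16 immediate early genes 15 had lower values (median -0.18, camera adjusted p = 1.9e-05; adjusted p = 0.391 with an estimated correlation), with Fosb at 12.8 against 47.4 CPM and Nr4a1 at 18.5 against 31.9 CPM, neither past the test. All of 12 cartilage markers and 10 of 11 adipocyte markers had lower values (medians -0.42 and -0.26; camera adjusted p = 0.000112 and 0.00763; adjusted p = 0.462 and 0.648 with an estimated correlation). Fibroblast markers had lower values too (median -0.09, mean -0.35; camera adjusted p = 0.000929; adjusted p = 0.391 with an estimated correlation), with Col1a1, 1 of the 2 called by DESeq2, at 2890 against 7323 CPM (edgeR adjusted p = 0.491). The neutrophil markers had a median of 0.55, or 0.32 at the floor (camera adjusted p = 0.0176; adjusted p = 0.813 with an estimated correlation). Krt6a, Krt16, S100a8, Cxcl1, Il1b and Prkca each had an edgeR adjusted p of 1.

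The fourth comparison asks what the loss of Krt17 changes in TPA-treated ear, where the study's title places a Krt17-dependent amplification of neutrophil influx. Neutrophil genes had lower mean values in null ears, a difference that passed only camera with the preset correlation, and single genes did not pass. Of 20 neutrophil markers all had lower values, with a median log2 difference of -1.29. Cxcr2 averaged 96.3 ± 63.9 CPM in null and 188 ± 56.8 CPM in wild-type TPA ears (edgeR adjusted p = 0.44), and Csf3r 203 ± 203 against 451 ± 179 CPM (edgeR adjusted p = 0.553). The smallest p belonged to Fpr1, the formyl peptide receptor gene, at 2.14 against 8.61 CPM (edgeR adjusted p = 0.279), and Mrgpra2b, uncertain because of its near-identical copy Mrgpra2a, at 0.909 against 3.21 CPM. None of the 20 passed in edgeR or DESeq2, and 4 had an unadjusted p under 0.05. Camera put the list below other genes with a preset correlation (adjusted p = 1.3e-08) and not with an estimated one (adjusted p = 0.687), fry gave an adjusted p of 0.269, and the exact permutation test of the list score gave p = 0.2, where 0.1 is the smallest possible. The list score was 2.69, 2.07 and 4.58 in the null TPA libraries and 4.15, 5.27 and 4.74 in wild type, so the groups overlapped. Without Krt17-null TPA replicate 3, 15 of the 20 were called lower (median -2.47). Fry then gave an adjusted p of 0.00658, and camera one of 0.0668 with an estimated correlation. Of the null libraries this one had the score closest to wild type, so leaving it out widens the difference. Values from this fit are therefore no independent test, and list results without each other TPA library are not given here.

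For the signals that draw neutrophils no list passed between the genotypes, and edgeR called none of their genes. Chemoattractants and growth factors had a median of -0.45 and inflammatory cytokines one of 0.10 (camera adjusted p = 0.432 and 0.445). The chemoattractant score was 3.88 ± 1.19 in null and 4.68 ± 0.336 in wild-type ears (n = 3 each, exact permutation p = 0.4), a spread that leaves room for a difference. At an unadjusted p under 0.05 there were 0 chemoattractants and 3 cytokines, and DESeq2 called 0 and 1, the latter Il1a, the interleukin-1 alpha gene, higher at 28.8 against 13.6 CPM (edgeR adjusted p = 0.191). Cxcl1 averaged 49.5 ± 27.2 CPM in null and 43.4 ± 12.4 CPM in wild type, S100a8 109 ± 82.8 against 133 ± 39.3 CPM, and Il1b 81.2 ± 70.6 against 137 ± 56.3 CPM, none past the edgeR test (adjusted p = 0.913, 0.92 and 0.753). Krt6a was at 2330 ± 924 against 3480 ± 1210 CPM (edgeR adjusted p = 0.594), and wound-activated and proliferation lists did not pass (camera adjusted p = 0.513 and 0.381). Of 9 endothelial markers 8 had lower values (median -0.60, camera adjusted p = 6e-07; adjusted p = 0.666 with an estimated correlation), with Cdh5, encoding VE-cadherin, at 36.3 against 68.6 CPM and Pecam1 at 70.8 against 114 CPM (edgeR adjusted p = 0.0845 and 0.161). Monocyte and macrophage markers had a median of -0.56 (camera adjusted p = 1.79e-05; adjusted p = 0.687 with an estimated correlation), with Cd68 at 71.6 against 150 CPM (edgeR adjusted p = 0.0799). Adjusted over the list alone, 4 endothelial genes were lower and 1 monocyte and macrophage gene was. Matrix proteases and hair follicle genes also had lower medians (-0.59 and -1.11; camera adjusted p = 9.56e-05 and 1.79e-05; adjusted p = 0.666 and 0.714 with an estimated correlation). Adipocyte and cholesterol synthesis genes had higher ones (0.65 and 0.28; camera adjusted p = 0.000104 and 5.34e-05; adjusted p = 0.687 for each with an estimated correlation), with Cidec, a lipid droplet gene, at 10 against 4.9 CPM, which edgeR did not call (adjusted p = 0.279) and DESeq2 did. In edgeR no gene of these lists passed, while 5 endothelial, 6 monocyte and macrophage, 6 matrix protease and 1 hair follicle genes had an unadjusted p under 0.05 and DESeq2 called 3, 1, 0 and 0 of them lower. Of the adipocyte and cholesterol synthesis genes 5 and 6 had an unadjusted p under 0.05, and DESeq2 called 1 and 0 higher. Without Krt17-null TPA replicate 3, 7 of 14 matrix protease genes were called lower (camera adjusted p = 0.0369 with an estimated correlation). In that fit 5 endothelial and 6 monocyte and macrophage genes were called lower as well. It left out the null library whose neutrophil score lay closest to wild type, so these values are no independent test.

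Single genes past the edgeR test in TPA ears were 3 higher and 4 lower. Krt17 was 68.9-fold lower (log2 -6.11, SE 0.22, edgeR adjusted p = 7.68e-10). Ifitm2, an interferon-induced membrane protein gene with near-identical pseudogenes and so uncertain, was at 81.7 ± 1.34 against 137 ± 6.35 CPM (edgeR adjusted p = 0.0192). The other 5 fell outside the rule for named genes and are given because the count is small. Gm4875 was 169-fold lower (edgeR adjusted p = 1.8e-07). Mcpt1, a mast cell protease gene, was at 1.28 ± 0.586 against 8.47 ± 0.942 CPM (edgeR adjusted p = 0.0268). Pck1 was at 4.72 ± 1.58 against 1.01 ± 0.47 CPM (edgeR adjusted p = 0.0192), Pkhd1l1 at 1.40 against 0.393 CPM (edgeR adjusted p = 0.048) and Mrgprb11-ps, a pseudogene of a receptor family whose counts are uncertain, at 2.01 against 0.294 CPM (edgeR adjusted p = 0.04). Ifitm2, Pck1, Mcpt1, Mrgprb11-ps and Pkhd1l1 lost the call in 6, 1, 4, 9 and 8 of 12 fits that left out 1 library. DESeq2 called 118 higher and 231 lower, including the same 7, and 2545 genes had an unadjusted p under 0.05. The counts were 422 higher and 995 lower without Krt17-null TPA replicate 3 and 72 and 98 without wild-type TPA replicate 1. They were 1 and 2 without Krt17-null TPA replicate 1 or wild-type TPA replicate 2 or 3, 7 higher without wild-type acetone replicate 1, and 1 higher without Krt17-null acetone replicate 3 or wild-type acetone replicate 2 or 3.

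The fifth comparison tests whether the genotypes differ in their response to TPA. The average response was smaller in Krt17-null ears, in replicates 1 and 2 of the null TPA group and little or not at all in replicate 3. Among 6284 genes raised by TPA on average over both genotypes, the null change was 0.733 of the wild-type change (slope through the origin), and among 5534 lowered genes it was 0.652. Median changes were 0.68 in null against 0.79 in wild type and -0.71 against -0.91. Noise lowers such a slope below 1, and with equal responses the standard errors of the model would give 0.960 and 0.940, a value that leaves out shifts shared by many genes of a library. The slope of wild type on null was 1.18 and 1.25, and both references were chosen after the result was seen. Mean log2 CPM of the raised set was 4.13, 4.15 and 4.47 in the null and 4.47, 4.54 and 4.43 in the wild-type TPA libraries, and that of the lowered set 2.92, 2.71 and 2.64 against 2.49, 2.51 and 2.63. The interaction was below 0 for the raised set and above 0 for the lowered set (camera p = 0.0175 and 0.0198 with an estimated correlation; fry p = 0.0457 and 0.0463; among genes called with a change of at least 2-fold, fry p = 0.0509 and 0.0304), while the exact permutation test of the set means in TPA ears gave p = 0.3 and 0.1. Glns-ps1 was the single gene called (log2 difference -4.29, SE 0.37, edgeR adjusted p = 0.00019). It averaged 0.568 CPM in wild-type acetone, 6.91 in wild-type TPA, 6.44 in null acetone and 3.98 in null TPA ears. No gene was called higher by edgeR, where 713 were higher at an unadjusted p under 0.05, and DESeq2 called 53 higher and 33 lower. Next by p were Ifitm2 (lower in its response), Loxl4, a lysyl oxidase gene (1.13), Pck1 (2.36) and Cilp2 (1.28), none past the edgeR test (adjusted p = 0.0607, 0.0607, 0.128 and 0.128). Krt17, Cxcr2, Csf3r and Il1b had log2 differences of -0.92, -1.51, -1.77 and -2.57 (edgeR adjusted p = 0.464, 0.727, 0.825 and 0.825).

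Some lists had a smaller response in null ears and some did not. Neutrophil markers had a median interaction of -1.67 (camera adjusted p = 3.04e-08, and 0.542 with an estimated correlation). Interferon-stimulated genes had one of -0.72 (camera adjusted p = 2.2e-06, and 0.542 with an estimated correlation). The mean interferon score, null minus wild type, was 0.63 under acetone and -0.20 under TPA, so most of that difference lay in the acetone ears. Adipocyte and cartilage markers, which fell with TPA, had medians of 0.83 and 0.83 (camera adjusted p = 6.62e-07 for each; adjusted p = 0.542 for each with an estimated correlation). Hair follicle, erythrocyte and mitochondrially encoded genes went the other way. Their medians were -0.25, -0.35 and -0.25 with TPA in wild type and -1.37, -0.57 and -0.34 for the interaction. Camera gave adjusted p = 0.000929, 0.0191 and 0.0204, and 0.558, 0.542 and 0.588 with an estimated correlation. The hair follicle score spread widely among null acetone libraries (1.05 ± 2.25, SD, n = 3). For TPA against acetone in null its exact permutation p was 0.4. Col1a1, a fibroblast collagen gene, had a log2 difference of 2.13 (edgeR adjusted p = 0.227) and Selp one of -1.34 (edgeR adjusted p = 0.431), neither past edgeR and both called by DESeq2. For the interaction DESeq2 called 3 fibroblast markers, 1 cartilage marker and 1 sebaceous gland gene higher, and 1 gene each lower among other chemokines, monocyte and macrophage markers, endothelial adhesion molecules and interferon-stimulated genes. EdgeR called none in these lists, where 4, 4, 3, 6, 5, 1 and 6 had an unadjusted p under 0.05. Leaving out Krt17-null TPA replicate 3 gave 125 genes higher and 395 lower, leaving out wild-type TPA replicate 1 gave 37 and 32, and leaving out wild-type acetone replicate 1 gave 16 and 2.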

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

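All tests of explanations here were chosen only after the results were seen, and tests of the Krt17 counts left in the null libraries were also run and are not weighed here. The neutrophil marker list had a lower mean in null than in wild-type TPA ears, with a score difference of -1.61 (SE 0.82, n = 3 and 3). A response weakened alike in all gene groups may account for it. The ratio of null to wild-type TPA effects averaged 0.928 over wound-activated, cytokine, NF-kB and proliferation lists against 0.665 for neutrophil markers. The gap of 0.263 (SE 0.151) leaves this undecided. Those lists also do not stand for all gene groups. By another measure, the slope of null on wild-type changes over all TPA-responsive genes, values were 0.733 for raised and 0.652 for lowered genes. A different make-up of the tissue pieces stays open, as no test here decides on it. A wild-type library in place of Krt17-null TPA replicate 3 is excluded, since its Krt17 was 34.1 CPM and the lowest wild-type TPA library had 2230 CPM.

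These tests were likewise chosen only after the calls were seen. Gm4875 was lower in null ears under both treatments. Reads of Krt17 assigned to it are excluded as a source, as the 2 transcripts share no aligned stretch longer than 12 bases. Reads of Lasp1 at a constant share in both genotypes are excluded too, as Lasp1 had a log2 difference of 0.12 under acetone and of -0.82 under TPA, where Gm4875 had -7.40, while a share that depends on a variant was not tested and stays open. A chromosome segment of another strain around the null allele stays undecided for the genotype calls. In the list of 25 Krt17 neighbours, 10 genes under TPA and 3 under acetone had an unadjusted p under 0.05 between genotypes. Among all 21775 genes tested, 2545 and 875 did. The score of that list, null minus wild type, was -0.159 under TPA and -0.132 under acetone (exact permutation p = 0.2 for each). Of 9 genes called under either treatment besides Krt17, 2 (Pyy and Glns-ps1) lay on its chromosome. That is 22.2% against 7.59% of 21063 tested genes (one-sided Fisher exact p = 0.145). Of 4 called for genotype averaged over both treatments, an added contrast, 3 did (these 2 and P3h4, 75%, one-sided Fisher exact p = 0.00165). P3h4 belongs to the list of Krt17 neighbours. Gm4875 was tallied off that chromosome by its own position. The chromosome of Lasp1, whose transcript it resembles, was not tallied.

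The Glns-ps1 tests were also chosen only after its call was seen. Its response to TPA differed between genotypes, with a log2 difference of -4.29. Reads of Glul assigned to it at a constant share could not produce its rise with TPA in wild type. There Glul had a log2 fold change of -1.19 and Glns-ps1 one of 3.59. A share that differs between treatments or genotypes was not tested and stays open. A variant linked to the null allele, or one that segregates between animals, was not tested and stays open.

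The next counts come from tests chosen after the results were seen, in which libraries were regrouped and every gene retested. The true grouping counts as 1 of the splits throughout. For TPA against acetone, 1 of 10 splits reached 9557 edgeR calls in wild type and 1 of 10 reached 7726 in Krt17 null. The highest other value was 0 calls in each. In the true grouping 11102 and 9743 genes had an unadjusted p under 0.05. Each other split put TPA and acetone libraries in the same group, where the treatment difference counts as spread. Its 0 calls are therefore no test of chance. For genotype under acetone 2 of 10 splits reached 5 calls, the highest other having 33. Under TPA 2 of 10 reached 7, the highest other, null replicates 1 and 2 with wild-type replicate 1, having 183. With 10 splits no share under 0.05 is possible. For the interaction 7 of 60 splits, the true grouping among them, reached 1 call, the highest other having 267. Some of the other splits kept the 3 libraries of a group together, so a real difference can add calls there. The tally also ignores how small the p of a call is, so it does not decide on Glns-ps1.

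The slope of null on wild-type responses was 0.733 for raised and 0.652 for lowered genes. Median log2 differences between the responses were -1.67 for neutrophil markers, -0.76 for other chemokines, -0.32 for monocyte and macrophage markers, -1.37 for hair follicle genes, -0.45 for endothelial markers and -0.57 for erythrocyte markers. They were -0.19 for proliferation genes, -0.72 for interferon-stimulated genes, -0.23 for NF-kB genes, -0.45 for matrix proteases, -0.58 for antimicrobial peptides and -0.34 for mitochondrially encoded genes. They were 0.25 for terminal differentiation genes, 0.20 for sebaceous gland genes, 0.83 for cartilage markers, 0.83 for adipocyte markers and 0.36 for cholesterol synthesis genes. Fibroblast markers had -0.0691, with a mean of 0.40. Each of these 18 lists passed camera with the preset correlation and none with an estimated one (smallest adjusted p = 0.542).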

How the results depend on the processing

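There were 21 alternatives (20 for the interaction), and some named genes, Mcpt1 among them, had no value in at least 1 of them. A call counted as kept where no alternative with a value for the gene lost or reversed it. Named calls kept in this sense were 103 of 146 for TPA in wild type and 85 of 148 in null. They were 3 of 5 for genotype under acetone, 2 of 7 under TPA and 1 of 1 for the interaction. Of 22, 23, 13, 12 and 18 list calls 20, 18, 6, 5 and 7 held in all fits, and 1, 2, 0, 0 and 0 with an estimated correlation. A 2-fold minimum gave 2477 higher and 2359 lower in wild type and 1830 and 1438 in null. The muscle covariate gave 1795 and 1331 in wild type and 1304 and 972 in null. It gave 1 higher for genotype under acetone, 10 under TPA and 1 for the interaction. As the muscle score fell with TPA in both genotypes, this covariate overlaps with treatment. No filter gave 9 higher under acetone, 50 and 58 under TPA, and 15 and 5 for the interaction. The strict filter gave 1 higher under TPA and 1 and 2 for the interaction. DESeq2 gave 15 and 10, 118 and 231, and 53 and 33. Voom gave 1 higher under acetone and 0 under TPA, and fits of 2 groups gave 5 and 4 under acetone and 0 and 2 under TPA. The surrogate variable gave 5 higher under TPA. Replicate number as a block gave 1 and 7 under TPA, but numbers did not pair libraries (r of deviations -0.119 to 0.0697 over 6 pairs).

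Leaving out 1 library gave 4168 to 5071 higher and 3827 to 4808 lower in wild type, 3138 to 4058 and 2799 to 3586 in null, 1 to 4 and 2 to 9 for genotype under acetone, 1 to 422 and 2 to 995 under TPA, and 0 to 125 and 1 to 395 for the interaction. Slopes ran from 0.609 to 0.804 and 0.556 to 0.748. Signs turned for Itga3 (-0.10), Tpsb2 (0.00226) and Mcpt4 (0.13) with the muscle covariate. For genotype under acetone the direction of camera turned for hair follicle genes (median 0.83) and skeletal muscle markers (-0.55) without Krt17-null acetone replicate 2 and for monocyte and macrophage markers (-0.28) without wild-type acetone replicate 1. The causes were not tested. In that comparison, Krt17 null against wild type under acetone, medians were -0.00487 for hair follicle genes and 0.32 for skeletal muscle markers without wild-type acetone replicate 3, and 0.011 for monocyte and macrophage markers without wild-type acetone replicate 2.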

Other observations

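This list and its test were chosen only after the Gbp5 call was seen. In Krt17-null ears given acetone, interferon-gamma target genes other than Gbp5 tended to higher values, and none of them passed alone. Among guanylate-binding protein genes, Gbp4 was at 11.4 against 3.75 CPM in wild type, Gbp7 at 17.7 against 8.98 CPM and Gbp2 at 14.3 against 6.52 CPM, none past the edgeR test (adjusted p = 0.376, 0.376 and 1). The 7 without Gbp5 all had positive log2 differences, with a median of 1.01 (camera p = 0.00107 with an estimated correlation; fry p = 0.00192), though related Gbp genes can share reads. Of 14 other targets all had positive values, among them the chemokine genes Cxcl9 and Cxcl10 (1.08 and 1.82) and the immunity GTPase genes Iigp1 and Igtp (1.78 and 0.90).

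As a hypothesis, the null acetone ears may have carried a wider interferon-gamma response. The interferon-stimulated list tended to higher values there too, so these genes do not tell gamma from other interferons. Tgtp1 and Tgtp2, both among the 14 other genes, are 99.8% identical and can share reads. The 14 other genes had a median of 0.445, with camera p = 0.0382 with an estimated correlation and fry p = 0.0584, and edgeR called 0 of them, so this stays undecided.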
